A study of Arabidopsis thaliana with 8 samples.

How the data were processed

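Leaves of Arabidopsis thaliana were profiled on a 1-colour 3' expression array with 22810 probe sets. The plants were wild type or carried VaMyb14, a Vitis MYB transcription factor gene under overexpression (VaMyb14-OE). Per the labels' protocols, plants grew on soil at 22 °C for 21 d, and cold-treated plants were then kept at 4 °C for 8 h. Leaf RNA of the VaMyb14-OE groups was a pool of independent transgenic lines. Total RNA was amplified and labelled with biotin as cRNA. Each of the 4 groups had 2 arrays, 8 in all.

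The authors deposited 1 linear intensity per probe set and array, from 3.93 to 17532. The software behind these intensities, the background correction and any scaling between arrays are not given in the sources used here. Array medians lay between 57.6 and 65.6. Samples were grouped by title, characteristics and treatment. One free-text field of the same samples names a drought treatment and another transgene (VaNAC26). The titles, source names, characteristics and protocol all name cold or VaMyb14, and these were followed.

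Intensities were turned to log2(value + 1) and quantile-normalized between arrays in limma 3.58.1 under R 4.3.3. The platform annotation listed 14016 probe sets, of which 13513 named 1 gene and 503 named several; 8730 further probe sets are unnamed here, and 64 are control probe sets. Probe sets naming several genes, unnamed ones and controls stayed out of the gene tests. Of the 13513 single-gene probe sets, 13436 matched an entry of the RefSeq gene table, which supplied current symbols. Genes without a symbol there are given by their locus. For genes with several probe sets, the one with the highest mean was used, which concerned 109 of the tested genes. Genes were kept where the probe set exceeded its array's 40th percentile on at least 2 arrays, which left 7735 of 13356 genes. The mean of that percentile was 5.04 on the log2 scale. No detection calls were used, so a group mean below that level is described as dim, and a fold change against it may understate the change.

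Each gene was fitted with 1 mean per group over all 8 arrays (lmFit), and the 5 contrasts of the design were tested with eBayes with an intensity trend. That left 4 residual and 5.86 prior degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 7735 genes, and 0.05 was the threshold. Errors given with log2 changes are the fit's standard errors (SE). The number of arrays limits the precision, and since the labels do not say that replicates came from separate plants or pools, p-values may measure a technical spread.

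Before the data were examined, 31 gene lists with 527 members were fixed. Through the annotation, 75 members were named on the array and 66 were measured, so 22 lists had a measured gene and 4 had at least 5, the minimum for the test. Those 4 were tested with camera at a preset inter-gene correlation of 0.01 and adjusted within each comparison, with an estimated correlation and fry as alternatives. Named genes followed a rule fixed at the same time. Per comparison it took the 10 largest rises and 10 largest falls among genes past the threshold whose groups of arrays did not overlap (for the difference between responses, the threshold alone), up to 4 members of each list with the smallest p, and genes passing in the same direction in both genotype comparisons. It also took a fixed set of MYB, CBF, COR, RD29 and LTP genes wherever measured, which among the named genes left COR15A.

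The procedure was tested on simulated arrays with each gene's mean over the 4 groups and its real spread, pooled over the groups. Simulated groups thus varied alike. Between real replicates the standard deviation ran from 0.170 in wild type cold to 0.278 in wild type control. The shares of false calls below therefore do not cover groups of unequal spread. Only the genes changed by design differed between the simulated groups, unlike in the real data. With 200 of 7735 genes changed in the wild type cold comparison, 67.1% of the genes changed by 1 on the log2 scale and 96.05% of those changed by 2 were recovered, and 4.37% of the calls were false. For the difference between the cold responses, the shares recovered were 32.6% and 83.5%, with 5.50% of the calls false. A simulated list of 10 genes shifted by 1 was found in 100% of 100 simulations, and an unshifted list in 1%. Simulated genes varied independently, so these shares do not cover lists whose genes vary together. The estimated inter-gene correlation was 0.518 in the phenylpropanoid and flavonoid list, against 0.0208 to 0.0562 in the other tested lists.

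Same-numbered replicates were checked for pairing by correlating deviations from the group means, and no pairing was used. Alternatives were another scaling (equal array medians), other filters, other rules for probe sets, a pseudocount of 16, other forms of eBayes, the 4 arrays of a comparison alone, a replicate block, a minimum change of 1 on the log2 scale, and leaving out each array. Where 1 array is left out, the remaining array of its group is assumed to vary like the other groups. Figures were drawn with matplotlib 3.10.9. No genome build is named by the files, so no coordinates are given.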

Results

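Transcript levels were measured in leaves of wild type and VaMyb14-OE Arabidopsis before and after 8 h at 4 °C. The series title names cold and drought tolerance, nonspecific lipid transfer protein (nsLTP) genes and abscisic acid signalling as its subject. The 4 groups were wild type control, wild type cold, VaMyb14-OE control and VaMyb14-OE cold, with 2 arrays each. The transgene itself has no probe set named here, so its level was not analysed here. Leaves were collected before and after the 8 h of cold, and no untreated leaves collected after those 8 h were analysed here. The changes described as cold responses therefore cannot be told apart from changes with elapsed time or time of day.

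The first principal component held 67.6% of the variance and separated the cold arrays from the control arrays. The second held 11.8% and separated VaMyb14-OE from wild type, with the wild type arrays at 1.84 or above and the VaMyb14-OE arrays at -8.24 or below. Replicates correlated across genes with r = 0.973 in wild type control, 0.990 in wild type cold, 0.977 in VaMyb14-OE control and 0.985 in VaMyb14-OE cold. The standard deviation between replicates was 0.278 on the log2 scale in wild type control, against 0.258 in VaMyb14-OE control, 0.209 in VaMyb14-OE cold and 0.170 in wild type cold. The ratio of 3' to 5' signal of the actin control transcript, a sign of RNA integrity and labelling, was 38.2 on wild type control replicate 1, 16 on replicate 2 and between 10 and 14.8 on the 6 arrays of the other groups. GAPDH and ubiquitin differed less, with ratios of 2.55 and 2.04 for GAPDH and 3.13 and 2.62 for ubiquitin on wild type control replicates 1 and 2. The 25S ribosomal RNA control probe set read 45.4 and 85.4 on the wild type control arrays and 485.4 to 1568 on the other 6.

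**Figure D1:**
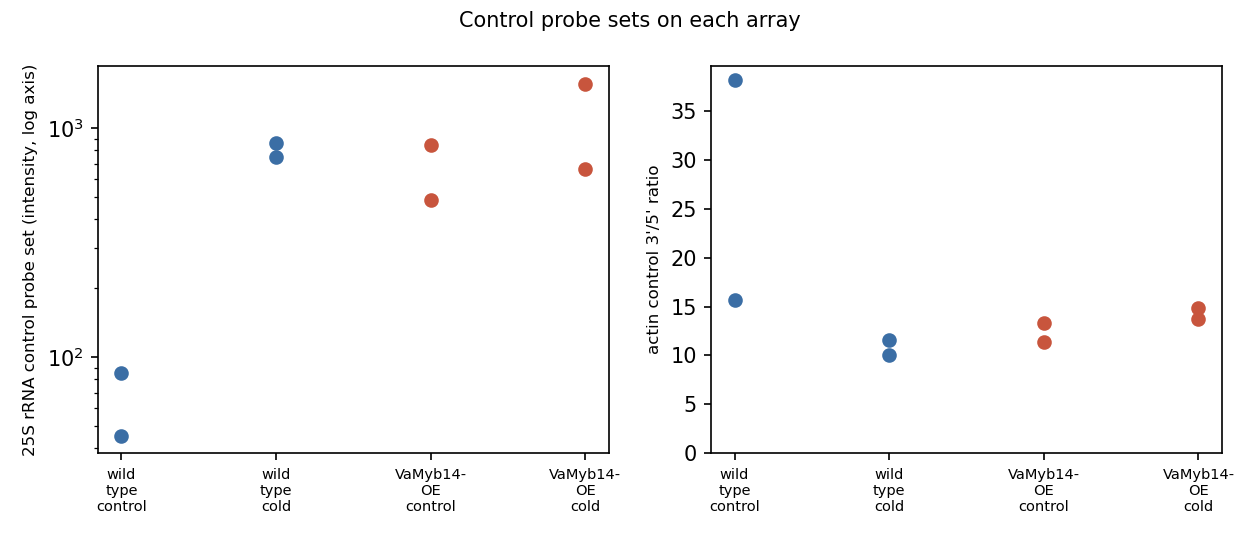
Intensity of the 25S ribosomal RNA control probe set (left, log axis) and ratio of 3' to 5' signal of the actin control transcript (right) on each of the 8 arrays, 1 point per array. Both wild type control arrays lie below 100 for 25S, and wild type control replicate 1 has the highest actin ratio, 38.2.

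The first comparison asked what 8 h of cold did to wild type leaves. All 4 measured cold-regulated (COR) genes rose. LTI30, a dehydrin, rose by 4.72 ± 0.30 (SE) on the log2 scale, a 26.4-fold change. COR47, another dehydrin, rose by 2.67, COR15B by 1.81 and COR15A, which encodes a chloroplast protein that protects membranes during freezing, by 1.69 ± 0.13. COR27, a cold- and clock-regulated gene, rose 20.7-fold. The largest rise among named probe sets was that of AT3G04010, 32.5-fold (adjusted p = 6.6e-07, limma), followed by LTI30, AT1G16850 at 26.2-fold, AT3G28310 at 25.5-fold and AT1G68500 at 24.4-fold. AT4G33980, AT3G55580, AT4G36010 and AT4G29610 rose 18.8- to 22.0-fold. The rise of AT4G29610 was 2.90 on the log2 scale without wild type control replicate 1 and 5.56 without replicate 2, and that of AT4G33980 3.65 and 5.27. AT3G28310, AT3G55580 and AT4G29610 were dim in control leaves.

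Genes of rapid stress and calcium responses rose in wild type in both measured cases. STZ, a zinc finger repressor, rose by 3.49 (2.31 without wild type control replicate 1) and CML38, a calmodulin-like protein gene, by 3.17. GI, an evening-phased clock gene and the single measured member of that list, rose by 1.2. Of 4 measured jasmonate genes, 3 fell. PDF1.2, a plant defensin gene used as a jasmonate marker, fell by 3.01 ± 0.49, an 8.07-fold change, and PDF1.2b fell by 1.94. The thionin gene THI2.1 fell by 2.09, a call lost without any 1 of the 4 wild type arrays (adjusted p from 0.057 to 0.193). OPCL1, a jasmonate synthesis gene, did not pass at 0.22. Among 4 auxin and cell expansion genes, EXPA8, an expansin gene, fell by 2.46, and WES1, which encodes an auxin-conjugating enzyme, fell by 2.83 with the call lost in 3 of the 4 leave-outs (adjusted p up to 0.0824). The largest fall was that of OSM34, an osmotin gene, at 20.5-fold (adjusted p = 0.0022), from 7.51 to a dim 3.15 on the log2 scale. AT3G26510 fell 12.8-fold, the serine carboxypeptidase-like gene scpl31 10.8-fold and AT2G03750 10.5-fold, and all 3 were dim in wild type cold leaves. The trichome patterning gene TRY fell by 1.45 and the glucosinolate gene UGT74B1 by 1.37.

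In the phenylpropanoid and flavonoid list, 2 of 8 measured genes rose and 2 fell in wild type. UGT78D2, a flavonoid glucosyltransferase gene, rose by 1.80 and CHIL, a chalcone isomerase-like gene, by 0.64, the latter not called without wild type cold replicate 2 (adjusted p = 0.113). DFR, which encodes the dihydroflavonol reductase of anthocyanin synthesis, fell by 1.71 ± 0.31 and UGT78D1 by 1.26 (-0.84 without wild type control replicate 1). Both measured starch breakdown genes, PWD and DPE1, were lower by -0.55 and -0.54, and both calls ended with equal array medians (adjusted p = 0.141 and 0.0931) and in 3 of 4 leave-outs. None of the 8 measured nsLTP and related genes passed the test, nor did any of 10 photosynthesis or 5 reactive oxygen scavenging genes, and 0 passed adjusted over each of those lists alone. The nsLTP list holds 29 genes, and those not measured include the LTP genes of the fixed set, so most of the list stayed untested. Of the nsLTP genes, AT4G12500 passed at -2.57 without wild type control replicate 1 (adjusted p = 0.00087) and AT1G62510 at 1.1 without replicate 2 (adjusted p = 0.00995). Camera found none of the 4 tested lists shifted in wild type (adjusted p = 0.977 for each). The nsLTP and photosynthesis medians, -0.05 and -0.01, turned to 0.11 and 0.21 with equal array medians. Without wild type control replicate 1 the nsLTP median was -0.454. The flavonoid list had a median of -0.11, although camera ranked its genes upward, and without that array the median was 0.412.

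**Figure D2:**
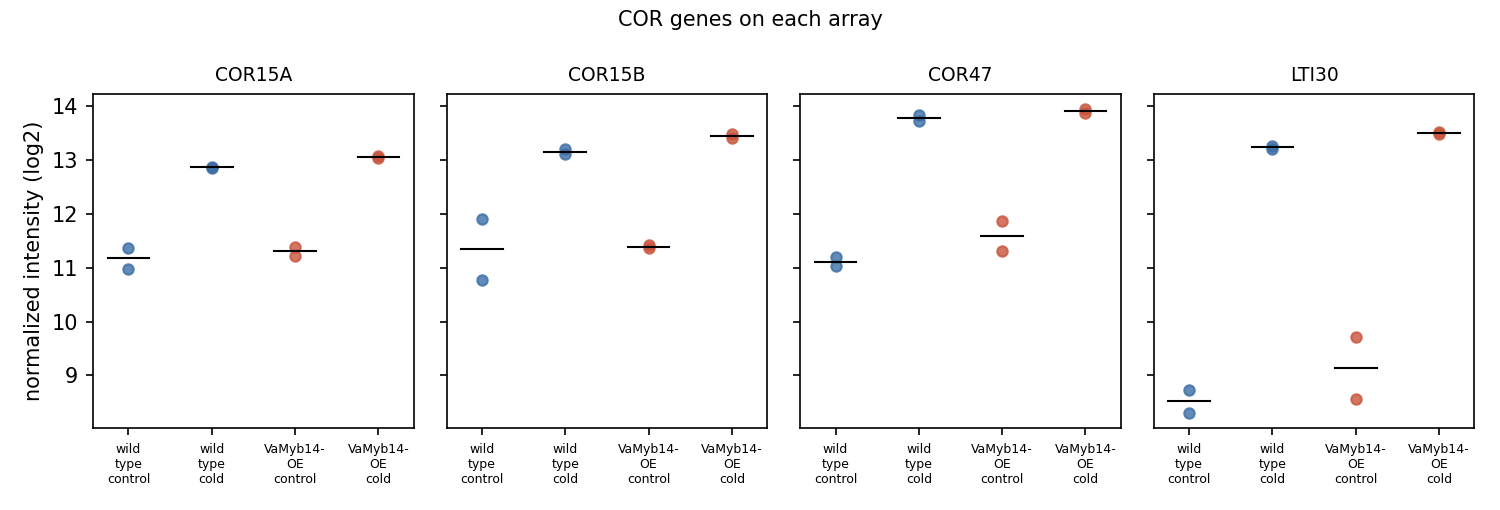
Normalized intensity (log2, vertical axis) of COR15A, COR15B, COR47 and LTI30 in the 4 groups, 1 point per array and a line at each group mean (n = 2 arrays). In both genotypes each cold array lies above each control array for all 4 genes.

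In all, 2012 of 7735 genes passed in wild type, 963 higher and 1049 lower in the cold, and 796 of them changed at least 2-fold. The scaling set the balance of directions. With equal array medians, which moved the median change of all genes from -0.05 to 0.05 on the log2 scale, 1173 genes were higher and 806 lower. The count fell to 890 without wild type cold replicate 1 and to 1168 without wild type cold replicate 2.

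The second comparison put the same question to VaMyb14-OE leaves. Again the 4 COR genes rose, LTI30 by 4.37, COR47 by 2.33, COR15B by 2.05 and COR15A by 1.75 ± 0.13. AT3G04010 had the largest rise, 36.3-fold, then AT3G55580 at 31.0-fold, AT1G32860 at 23.3-fold and AT1G16850 at 21.0-fold. AT2G16890, AT1G48100, AT5G47060 and AT1G68500 rose between 15.8- and 19.6-fold, and COR27 16.6-fold. The largest falls were those of AT4G33666 and EXPA8, both 12.3-fold, followed by AT2G20670 at 11.4-fold, AT5G19120 at 10.6-fold and AT2G03750 at 9.57-fold. AT3G55580 was dim in control leaves of this genotype, and AT2G20670 and AT2G03750 were dim in its cold leaves.

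LEA4-5, a late embryogenesis abundant protein gene and the single measured member of the abscisic acid and drought list, rose by 2.80 ± 0.64 in VaMyb14-OE. That call was lost without VaMyb14-OE cold replicate 2 (adjusted p = 0.0982), and the rise was 1.61 without VaMyb14-OE control replicate 2. WRKY53, a defence and senescence regulator, rose by 1.95, a call lost in 2 of 4 leave-outs (adjusted p up to 0.123). Neither rise was shown to be particular to VaMyb14-OE. In wild type, LEA4-5 stood at 0.74 (limma adjusted p = 0.42) and WRKY53 at 1.09 (adjusted p = 0.107). The unadjusted p of WRKY53, the single measured gene of its list, was below 0.05 there, and it stood at 1.77 without wild type control replicate 2. The responses of LEA4-5 and WRKY53 differed by 2.05 and 0.86 between the genotypes without passing over all genes (limma adjusted p = 0.537 and 0.661). The unadjusted p of LEA4-5 was below 0.05. STZ rose by 2.44, which was lost in 3 of 4 leave-outs, and CML38 did not pass at 1.07, although it did at 1.74 without VaMyb14-OE control replicate 2 (adjusted p = 0.0188). OPCL1 rose by 0.89. The other jasmonate genes did not pass, with PDF1.2 at -1.38, PDF1.2b at -0.90 and THI2.1 at 0.34, but each did without some array. Without VaMyb14-OE control replicate 1, PDF1.2 passed at -1.86 (adjusted p = 0.0477) and THI2.1 at 1.71 (adjusted p = 0.0047). Without VaMyb14-OE cold replicate 2, PDF1.2 passed at -2.21 (adjusted p = 0.0117) and PDF1.2b at -1.5 (adjusted p = 0.0402). GI rose by 1.35. Of the 8 phenylpropanoid and flavonoid genes, UGT78D2 rose by 2.1 and AT5MAT, an anthocyanin malonyltransferase gene, by 0.99, a call lost in 3 of 4 leave-outs. DFR did not pass at 0.63. TRY, UGT74B1 and the guard cell gene AT1G22690 (listed as GASA9) changed by -0.86, -0.97 and -1.07, and none of these calls held in every leave-out. The change of AT1G22690 lay between -1.46 and -0.68 in the leave-outs.

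Of 8 nsLTP and related genes, AT2G45180 fell in VaMyb14-OE by 0.34 on the log2 scale (adjusted p = 0.0133, limma) and 7 did not pass. With equal array medians its change was -0.16 and missed the threshold (adjusted p = 0.312), and the call was also lost without either VaMyb14-OE cold array (adjusted p up to 0.0612) and without the dim filter (0.0508). The photosynthesis list had 2 lower genes of 10, LHCB4.2 at -0.55 and PSBY at -0.35, the latter lost with equal array medians (adjusted p = 0.319), without the dim filter (0.0525) and in 2 of 4 leave-outs. SAPX, a stromal ascorbate peroxidase gene, was lower by -0.48 among 5 oxygen scavenging genes, a call lost in 3 of 4 leave-outs, with equal array medians (adjusted p = 0.1) and without the dim filter (0.051), and GR1 passed at 0.53 with equal array medians (0.0291). No list was shifted by camera over all 8 arrays. The flavonoid list had the smallest adjusted p at 0.0652, and it passed in 5 of the 8 fits that left out 1 array (adjusted p from 0.0457 to 0.169). In all, 1968 genes passed in VaMyb14-OE, 925 higher and 1043 lower, and 773 changed at least 2-fold. With equal array medians 1012 were higher and 824 lower, so the larger side turned here too. The count was 1223 without VaMyb14-OE control replicate 1 and 1021 without VaMyb14-OE cold replicate 1.

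The 2 cold responses, which share no array, were then set side by side. Of the genes tested, 640 rose in both genotypes, where independent lists would share 115.2, and 573 fell in both, against 141.4. Both tests used the same estimate of each gene's spread, so the lists were not fully independent. AT3G04010, LTI30, AT1G16850, COR27 and AT1G68500 were among the 10 largest rises in each genotype. Across genes, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.834 and Spearman's rho = 0.720. The median ratio of the VaMyb14-OE to the wild type change was 1.02 over the 1213 genes that passed in the same direction. That choice leaves out genes that passed in a single genotype, so the ratio does not compare the responses as a whole. Of 798 genes that passed in wild type alone, 713 had the same direction in VaMyb14-OE, and of 754 that passed in VaMyb14-OE alone, 695 had the same direction in wild type.

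**Figure D3:**
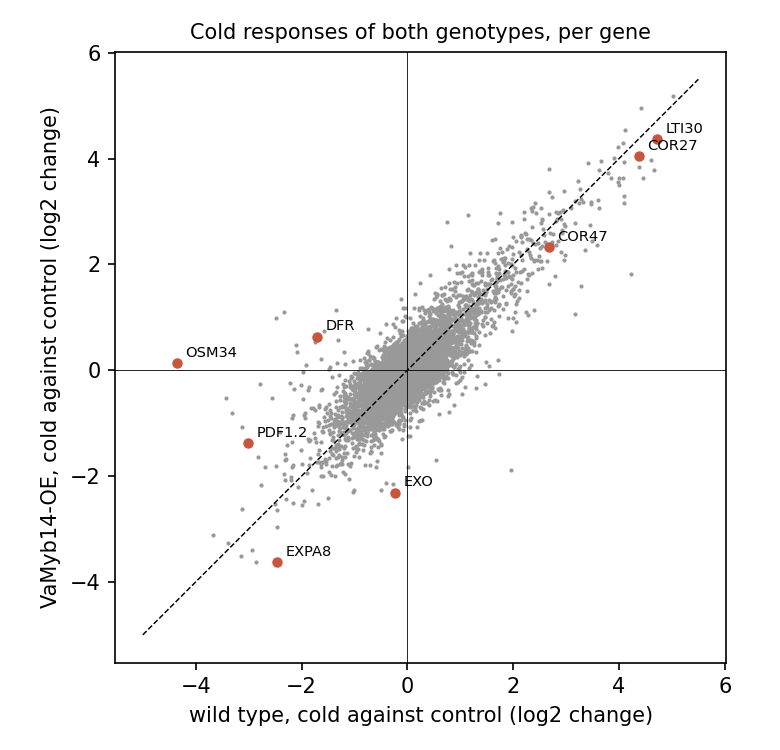
Log2 change in the cold of each of the 7735 genes in wild type (horizontal) and VaMyb14-OE (vertical), 1 point per gene, with the line of equal change dashed and 8 genes named. LTI30, COR27 and COR47 lie near the line, while EXO fell in VaMyb14-OE and lay near 0 in wild type.

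The test of the difference between the cold responses passed for 1 gene. EXO, a growth gene that responds to brassinosteroids, changed by -2.08 ± 0.23 more in VaMyb14-OE than in wild type on the log2 scale (adjusted p = 0.0309, limma). Its group means were 7.78 in wild type control, 7.55 in wild type cold, 8.60 in VaMyb14-OE control and 6.28 in VaMyb14-OE cold. Leaving out 1 array ended this call in 6 of 8 cases (adjusted p from 0.0152 to 0.348), although the difference stayed between -1.94 and -2.22. At an unadjusted p below 0.05 there were 719 genes, where chance alone gives 386.8. COR15A differed by 0.06 ± 0.19 and did not pass, and neither did any other COR gene.

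The phenylpropanoid and flavonoid list shifted upward in the difference between the responses, with a median of 0.80 over 8 genes (camera adjusted p = 0.00489). With an estimated correlation the shift was not found (adjusted p = 0.389), nor was it without wild type control replicate 1 (median 0.235, adjusted p = 0.082). None of its genes passed over all genes, and 3 did adjusted over the list alone. The differences were 2.34 for DFR, 1.52 for AT4G14090 (entered in the list as UGT75C1, an anthocyanin glucosyltransferase gene), 0.95 for AT5MAT and -0.62 for CHIL. Without VaMyb14-OE control replicate 1, DFR passed at 2.72 (adjusted p = 0.0446), as did the nsLTP gene AT5G01870 at 2.88 (adjusted p = 0.0313) and THI2.1 at 3.81 (adjusted p = 0.0126). Photosynthesis genes had a median difference of -0.16 and did not pass (camera adjusted p = 0.0531), with -0.103 without wild type control replicate 1. They passed with equal array medians (median -0.271, adjusted p = 0.00971), without VaMyb14-OE control replicate 1 (0.0141) and without VaMyb14-OE cold replicate 1 (0.0286), but not with an estimated correlation (0.389). The nsLTP list (median 0.36, adjusted p = 0.48) and the oxygen scavenging list (median -0.13, adjusted p = 0.773) did not pass either. Without wild type control replicate 1 the nsLTP list passed at a median of 0.608 (adjusted p = 0.00866), as it did at 0.472 without VaMyb14-OE control replicate 1 (0.0141). The oxygen scavenging median was -0.0515 without wild type control replicate 1 and -0.254 with equal array medians.

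**Figure D4:**
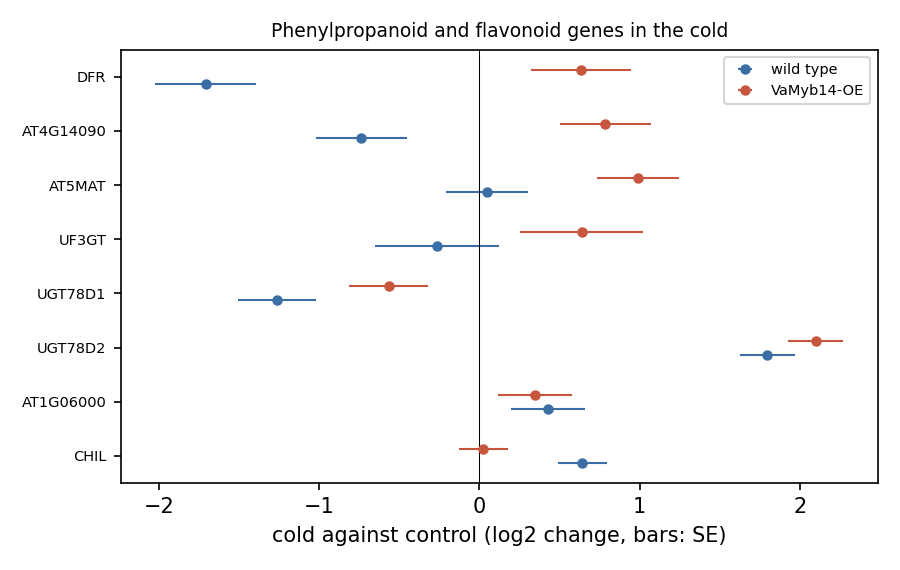
Log2 change in the cold (horizontal) of the 8 measured phenylpropanoid and flavonoid genes in wild type and VaMyb14-OE, as points with bars of 1 SE (2 arrays per group). DFR stood at -1.71 in wild type and 0.63 in VaMyb14-OE, and UGT78D2 rose in both.

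Before cold, VaMyb14-OE leaves differed from wild type in 4 genes. QQS, an Arabidopsis orphan gene linked to starch content, was 4.19-fold higher in VaMyb14-OE, a log2 difference of 2.07 ± 0.24 (adjusted p = 0.028, limma). The plastid gene psaA, for a core protein of photosystem I, was 3.29-fold higher and AT1G67870 2.19-fold higher. Another plastid photosystem I gene, psaJ, was 4.46-fold lower. The difference of QQS stayed between 1.71 and 2.42 in the 4 leave-outs of these arrays. In a fit of the 4 control arrays alone no gene passed, so the QQS call also drew on the spread among the cold arrays. Without wild type control replicate 1, the array with the high actin ratio, psaA (adjusted p = 0.0509), psaJ and AT1G67870 (both 0.158) did not pass. AT1G67870 also missed the threshold without VaMyb14-OE control replicate 2 (adjusted p = 0.0677) and with equal array medians (0.0875). Both plastid genes stood beside the lower 25S signal of the wild type control arrays.

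None of the COR genes passed before cold, with LTI30 at 0.62, COR47 at 0.48, COR15A at 0.13 and COR15B at 0.05. Without VaMyb14-OE control replicate 2, LTI30 passed at 1.2 on the log2 scale (adjusted p = 0.0316) and COR47 at 0.76 (adjusted p = 0.0327), and without wild type control replicate 2 COR15B passed at 0.61 (adjusted p = 0.0231). None of the 8 nsLTP and related genes passed, the largest differences being -1.88 for AT5G01870 and 1.78 for AT4G33550. AT5G01870 passed at -3.30 without VaMyb14-OE control replicate 1 (adjusted p = 0.0123), AT4G33550 at 3.27 without VaMyb14-OE control replicate 2 (adjusted p = 0.0139) and AT1G62510 at 1.23 without wild type control replicate 2 (adjusted p = 0.0325). WRKY53 stood at 1.56, STZ at 1.68 and CML38 at 1.3, none past the test over all genes. STZ and CML38 passed adjusted over their list of 2 measured genes. WRKY53, the single measured gene of its list, had an unadjusted limma p below 0.05. Without wild type control replicate 2, WRKY53 passed at 2.23 (adjusted p = 0.0289) and STZ at 2.86 (adjusted p = 0.00576). The 8 flavonoid genes had a median of 0.01, or 0.309 without wild type control replicate 1. Camera found no list shifted (smallest adjusted p 0.797), and the flavonoid list upward without that array (adjusted p = 0.000577). The count of 4 ranged from 0 to 219 as single arrays of the 8 were left out. It was 219 without wild type control replicate 2, 27 without VaMyb14-OE control replicate 1, 18 without VaMyb14-OE control replicate 2, 1 without wild type control replicate 1, 2 without either wild type cold array and 0 without either VaMyb14-OE cold array. At an unadjusted p below 0.05 there were 662 genes, against 386.8 by chance.

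After cold, 71 genes differed between the genotypes, 44 higher and 27 lower in VaMyb14-OE, and 40 of them at least 2-fold. AT3G53980 was 12.0-fold higher (log2 3.59 ± 0.67, adjusted p = 0.0472, limma). HIS1-3, a drought-inducible linker histone gene, was 8.63-fold higher and AT5G39520 8.58-fold higher, both dim in wild type cold leaves. AT1G54020 was 6.13-fold, WRKY53 5.34-fold, AT3G28270 5.13-fold and DFR 4.94-fold higher. AT4G14020, AT4G01390 and AT3G02840 were 4.16- to 4.45-fold higher. DFR and AT3G02840 were also dim in wild type cold leaves, and the call of AT3G02840 ended with equal array medians (adjusted p = 0.0506). AT1G67870, higher before cold too, was 2.32-fold higher. Independent lists would share 0.017 genes in that direction, but both tests used the same estimate of each gene's spread, so these lists were not independent.

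Lower in VaMyb14-OE after cold were psbI, a plastid photosystem II gene, at 4.89-fold, and AT4G37240 at 3.14-fold (adjusted p = 0.0039). AT1G22690 was 2.55-fold lower, the thionin gene THI2.2 2.50-fold, AT5G49170 2.43-fold and EXO 2.41-fold. AT3G28310, AT5G01015, AT3G06770 and AT4G32460 were 2.09- to 2.25-fold lower.

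**Figure D5:**
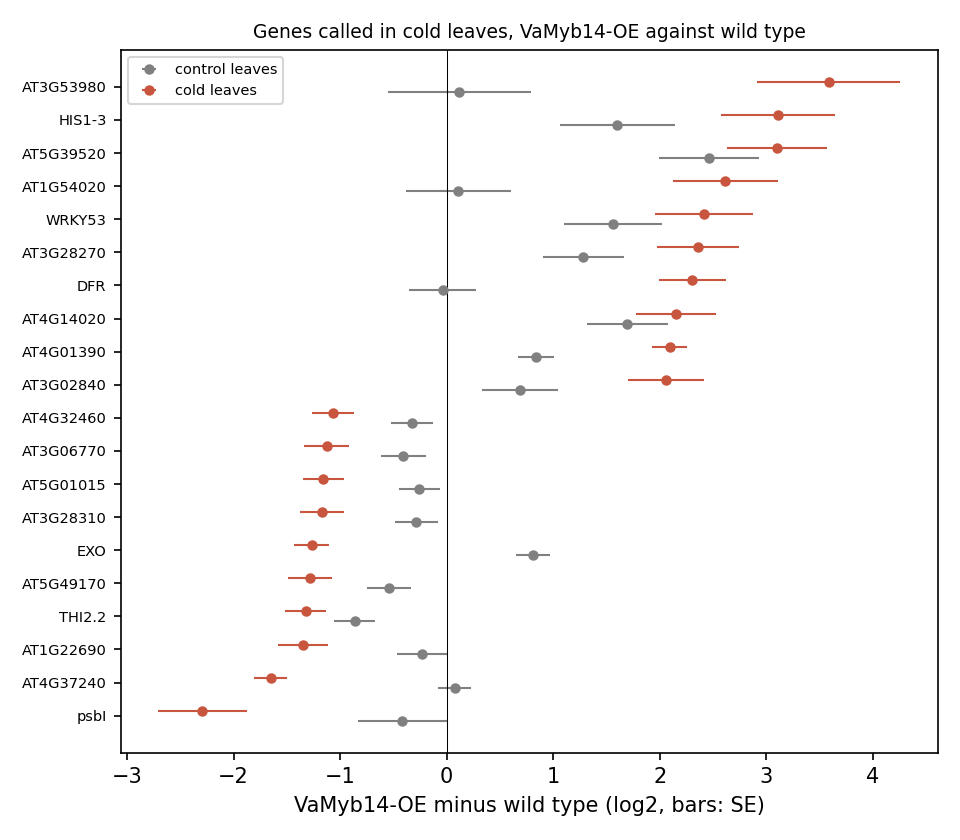
Log2 difference between VaMyb14-OE and wild type (horizontal) for the 10 genes most raised and 10 most lowered in cold leaves, in control leaves (grey) and cold leaves (red), as points with bars of 1 SE (2 arrays per group). HIS1-3 and WRKY53 lie above 0 in both, and EXO lies above 0 in control leaves and below 0 in cold leaves.

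By list, 2 of 8 phenylpropanoid and flavonoid genes were higher in VaMyb14-OE after cold, DFR by 2.3 ± 0.31 and AT4G14090 by 1.62, and AT5MAT did not pass at 1.0. The list as a whole was shifted upward (median 0.66, camera adjusted p = 0.00252; adjusted p = 0.318 with an estimated correlation). Photosynthesis genes were shifted downward with a median of -0.17 over 10 genes (camera adjusted p = 0.0152; adjusted p = 0.318 with an estimated correlation and 0.0894 without VaMyb14-OE cold replicate 2), and none of them passed singly over all genes, against 2 adjusted over the list alone. WRKY53 was the single measured salicylate and defence gene. The 4 jasmonate genes stood higher, THI2.1 at 2.62, PDF1.2 at 1.60, PDF1.2b at 1.19 and OPCL1 at 0.62. None of them passed over all genes, and 4 did adjusted over the list alone. LEA4-5 stood at 2.67 and missed the threshold (adjusted p = 0.079).

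None of the 8 nsLTP and related genes passed after cold, although AT4G33550 stood at 2.89 (adjusted p = 0.09) and AT4G12500 at 2.33 (adjusted p = 0.097), and 2 passed adjusted over the list alone. The list was not shifted over all 8 arrays (camera adjusted p = 0.203), but passed without either wild type control array, which changed the estimated spread and not its median of 0.18 (adjusted p up to 0.0354). Differences of the COR genes lay between 0.13 and 0.28, and none passed. These gene and list differences stood beside a difference in the control transcripts, with actin 3' to 5' ratios of 14.8 and 13.7 on the VaMyb14-OE cold arrays and 10 and 11.6 on the wild type cold arrays. None of the 71 calls held in each of the 4 leave-outs of these arrays, although all 71 kept their direction. The count was 1 without wild type cold replicate 1, 0 without replicate 2, 1 without VaMyb14-OE cold replicate 1 and 2 without replicate 2, but 324 in a fit of the 4 cold arrays alone. It was 163 without wild type control replicate 1 and 170 without wild type control replicate 2.

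Other lists held 1 to 3 measured genes that passed in none of the 5 comparisons over all 8 arrays. These were the CBF pathway gene SIZ1, the wax gene WSD1, the senescence gene SAG29, the sucrose synthesis gene ATSPS4F and 3 heat shock genes. SIZ1, SAG29 and ATSPS4F were each the single measured gene of their list, so adjusting over the list alone corrected nothing. Their unadjusted limma p was below 0.05 between the genotypes after cold, at 0.42, 1.12 and 0.89, as was that of 1540 genes in all. For SAG29 it was below 0.05 before cold too, at 1.19. The heat shock gene AT5G48570 passed in wild type in the cold at -0.99 without wild type control replicate 2 (adjusted p = 0.00881). The 3 reference genes GAPC2, AT4G34270 and AT2G28390 also passed in none, with changes between -0.32 and 0.27, and GAPC2 passed adjusted over its list alone in VaMyb14-OE in the cold. Among the dark-induced genes AT5G38710 rose in VaMyb14-OE in the cold by 0.81 (adjusted p = 0.0386), a call lost in 2 of 4 leave-outs and without the dim filter (0.0523). A further 9 lists had no measured gene named here, among them abscisic acid synthesis and signalling and the markers of root, flower and seed, so these were not analysed here.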

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

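The tests on the 3' to 5' ratios of the control transcripts and on an exchanged label were chosen only after the results were seen.

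Before cold, the plastid genes psaA and psaJ passed between the genotypes in opposite directions, on arrays that differed in 25S ribosomal RNA. The 25S control probe set, which stood outside the gene tests and above its level in wild type control, read 12.9-fold higher in wild type cold, 10.3-fold in VaMyb14-OE control and 16.3-fold in VaMyb14-OE cold. Carry-through of RNA without poly(A) tails would raise most plastid transcripts in VaMyb14-OE control, and a share of 0.587 of 63 was higher there (95% bootstrap interval over genes 0.46 to 0.698), while psaJ was lower. An effect of VaMyb14 would give plastid genes like differences before and after cold, and rho across them was 0.221 (interval -0.0376 to 0.468). Both intervals lay below the size set for a cause of the whole pattern but reached past the bound set for its absence, so as partial causes the explanations cannot be told apart.

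After cold, 71 genes passed between the genotypes, and none did so in every leave-out. Both VaMyb14-OE cold arrays had higher 3' to 5' ratios than both wild type cold arrays on 4 of 5 control pairs (actin 14.8 and 13.7 against 10 and 11.6), so degraded RNA could differ with genotype here. Those 4 were pairs of actin and GAPDH, and the ubiquitin pair did not separate the groups. Spearman's rank correlation of the genotype difference with that between the wild type control replicates was -0.0776 over the 71 genes (interval -0.379 to 0.196). That lay under the size set for a cause of the whole pattern, but the interval reaches past the bound set for its absence. An effect of VaMyb14 present also before cold would give the same sign there. A share of 0.817 of the 71 had it (interval 0.718 to 0.901), with no arrays in common between the comparisons. Before cold the 4 pairs stood the other way, with both wild type control arrays above both VaMyb14-OE control arrays (actin 38.2 and 16, against at most 14.8 elsewhere). Degradation would thus give the opposite sign before cold, so the share of 0.817 argues against it for most of the 71 genes. That reading of the share was not set beforehand, and no share over all genes was taken for comparison. As a cause of part of the pattern, degradation stays open. As a hypothesis, part of the genotype difference may thus precede the cold, while a difference in how the leaves were grown or pooled was not tested.

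The wild type control replicates lay farther apart than the other pairs, with a standard deviation of 0.278 against 0.258 in VaMyb14-OE control. The cold pairs stood at 0.209 in VaMyb14-OE and 0.170 in wild type. The VaMyb14-OE control arrays had actin ratios of 13.3 and 11.4, so a spread almost as large arose there without a high ratio. Wild type control replicate 1 had the highest 3' to 5' ratio on 5 of 5 pairs of control probe sets, so degraded RNA or uneven labelling on that array is a candidate cause. The pairs cover only actin, GAPDH and ubiquitin, so they are not 5 independent signs. An exchanged label with a cold sample would align the difference between these replicates with the cold response, and their r across genes was -0.0271 (interval -0.0559 to 0.00204), which argues against it. Ordinary variation between plants was not tested and stays open.

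EXO was singled out because its cold responses differed between the genotypes by test, at -2.08. The phenylpropanoid and flavonoid list was singled out in the same way, with a median difference of 0.799. That shift was not found with an estimated correlation (camera adjusted p = 0.389), and the median was 0.235 without wild type control replicate 1.

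Probe sets unnamed here, which the gene comparisons leave out, held rises in the cold larger than those of any named gene. Of these, 1 probe set rose by 6.12 in wild type and 6.54 in VaMyb14-OE on the log2 scale, and the largest other rises were 6.33 in wild type and 6.15 in VaMyb14-OE. Between the genotypes after cold, the largest differences of unnamed probe sets were 3.31 and 2.74.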

How the results depend on the processing

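All alternatives were planned except leaving out the plastid-encoded genes and the gene families, which were chosen after the data were seen. Named genes were followed under equal array medians, without the dim filter, with the replicate block and in the leave-outs, and none that passed reversed its direction there; the other alternatives were compared by counts. Equal array medians ended 2 named calls in wild type cold, 3 in VaMyb14-OE cold, 1 before and 1 after cold, and dropping the dim filter ended 4 in VaMyb14-OE cold, AT2G45180, SAPX, PSBY and AT5G38710 (adjusted p from 0.0508 to 0.0525). Of the calls, 768 of 2012 in wild type cold, 834 of 1968 in VaMyb14-OE cold, 1 of 4 before cold, 0 of 71 after cold and 0 of 1 in the difference between responses held in every leave-out of their arrays, and all kept their sign. Testing every probe set (14325) gave 3730 calls in wild type cold, 3547 in VaMyb14-OE cold, 1 before cold and 0 in the difference. A minimum change of 1 left 796, 773 and 40 calls in wild type cold, VaMyb14-OE cold and between genotypes after cold, and overlaps of 354 higher and 154 lower. Without the intensity trend there were 2 calls before and 47 after cold, and robust eBayes gave 2 in the difference. The 4 arrays of a comparison alone gave 0 before and 324 after cold. The filter at the 60th percentile left 43 calls after cold of 5265 genes tested. Equal array medians gave 2 in the difference. Without plastid-encoded genes 1 call was left before cold. The genes removed include psaA and psaJ, which were among the 4. Their removal also changed the ranks used to adjust the p-values of the other genes, and this was not separated from other effects of the new fit.

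Leaving out 1 array gave 890 to 2246 calls in wild type cold, 1021 to 2297 in VaMyb14-OE cold, 0 to 219 before cold, 0 to 170 after cold and 0 to 33 in the difference. The number of shifted lists, 0 in wild type cold under every setting run, ranged over leave-outs from 0 to 1 in VaMyb14-OE cold, 0 to 1 before cold, 1 to 3 after cold and 1 to 3 in the difference. An estimated correlation gave 0 lists after cold and 0 in the difference. Fry gave 1 in VaMyb14-OE cold, 1 after cold (photosynthesis in both) and 0 in the difference, where equal array medians gave 2, photosynthesis being added. Apart from the smaller sets of genes or arrays, the cause was not tested.

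Same-numbered replicates did not deviate together (correlations from -0.186 to 0.22), so the numbers pair nothing. With the replicate number as a block the counts were 2108 in wild type cold, 2065 in VaMyb14-OE cold, 7 before cold, 96 after cold and 3 in the difference, with 2 lists shifted in the difference, photosynthesis again being added. No named call was lost, and named genes that had not passed did so with the block, 1 in wild type cold (GH3.3), 4 in VaMyb14-OE cold (PDF1.2, PDF1.2b, WES1 and CML38) and 2 after cold (THI2.1 and LHCB4.3).

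Signal limits the dim genes. With no detection calls, changes against a mean below 5.04 on the log2 scale, as for OSM34 and HIS1-3, may be understated. Equal array medians gave 1979 calls in wild type cold, close to the 2012, but moved the share of higher calls from 47.86% to 59.27%.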

Other observations

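The grouping of genes by symbol into 16 families was chosen after the values were seen. The 63 measured plastid-encoded genes shifted upward in the cold in both genotypes. In wild type 18 rose and 1 fell, with a median of 0.39 (camera adjusted p = 1.3e-05; adjusted p = 0.904 with an estimated correlation). The ATP synthase gene atpI changed by 2.28, the NADH dehydrogenase-like complex gene ndhD by 2.00 and psaJ by -1.63. In VaMyb14-OE 15 rose and 4 fell, with a median of 0.41 (camera adjusted p = 1.3e-05; adjusted p = 0.816 with an estimated correlation). There ndhD changed by 1.54, and psbI, psbN, atpA and psbK by -2.15, -1.88, -1.83 and -1.69. With equal array medians the medians were 0.55 and 0.49. In wild type these rises stood beside a 12.9-fold higher 25S signal in cold than in control arrays, whereas the 25S signal of VaMyb14-OE was 10.3-fold above wild type control before cold and 16.3-fold after it.

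Of 13 cytochrome P450 genes with CYP symbols, 5 fell in wild type in the cold, among them CYP71B22 at -1.08, CYP71B6 at -1.02, CYP71B28 at -1.02 and CYP71B26 at -0.94. The family median was -0.40 (camera adjusted p = 0.0302; adjusted p = 0.904 with an estimated correlation). After cold, 12 of the 13 stood higher in VaMyb14-OE than in wild type, with a median of 0.38 (camera adjusted p = 0.000899; adjusted p = 0.65 with an estimated correlation), and none passed singly in limma. Before cold, 14 serine carboxypeptidase-like (SCPL) genes had a median of -0.23 in VaMyb14-OE against wild type (camera adjusted p = 0.0109; adjusted p = 0.929 with an estimated correlation), or -0.139 without wild type control replicate 1. After cold, the PRA family (10 genes) had a median of -0.29 and the UBP family (12 genes) 0.21 (camera adjusted p = 0.0179 and 0.0409; adjusted p = 0.65 with an estimated correlation for both). None of the SCPL, PRA or UBP genes passed singly in limma in these comparisons.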
